A study of Mus musculus with 8 samples.

How the data were processed

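Gene expression was measured by RNA sequencing of total RNA from NK cells in 8 libraries, 2 each of wild-type ex vivo, CIS-null ex vivo, wild-type in vitro and CIS-null in vitro cells. Per the submitters' processing notes, the authors aligned reads to GRCm38/mm10 with Subread, counted them over genes with featureCounts and normalised them with limma. The notes give no version or counting setting. The deposited matrix holds raw read counts for 27179 Entrez genes, 565 of them without a symbol. The deposited per-sample files hold log2 RPKM values, as the authors computed them, for 12372 genes. Counts were used for all comparisons, and log2 RPKM only for 1 alternative. Strand and the handling of reads shared by overlapping genes or paralogs were not stated, so values of such genes are uncertain. Library totals ran from 21.5 to 28.1 M counts.

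Gene positions came from a GRCm38.p6 gene table, which matched 25275 identifiers (93.0%), and 97.8% of the 12285 with over 100 counts. Gene lengths came from the deposited count matrix, and base composition from the longest GENCODE transcript of each gene. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 13184. Scaling used the trimmed mean of M values, and all 8 libraries were fitted together with 1 mean per group (4 residual degrees of freedom, prior degrees of freedom 4.45, common dispersion 0.0141). Quasi-likelihood F tests were made for 5 comparisons: genotype ex vivo, genotype in vitro, their difference (the interaction), and culture in each genotype. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F.

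Where a compared group held 0 counts, the fold is a lower bound from a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with a 95% counting interval. Floors and intervals cover counting error only. Gene lists were written before the data were examined: 31 lists, of which 30 had at least 5 tested genes and were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Camera with an estimated correlation and fry are given beside it. Each list's members were also adjusted over the list alone. Genes called near Cish were counted within 10 Mb and compared with the other genes by a two-sided Fisher's exact test, with 5 and 20 Mb as alternatives.

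Genes were named by a rule set in advance. Cish was named in every library. For a genotype comparison with at most 30 calls every gene with a symbol was named, and otherwise the 12 per direction with the largest change, a mean of at least 5 CPM and non-overlapping libraries, with up to 5 next in order where under 5 passed. For culture in wild-type cells 10 per direction were named, at 20 CPM or more. For the interaction 8 per direction were named by lowest p. For each list up to 4 passing members were eligible. Predicted genes were counted and not named, except where a difference between states passed. Members named because few in a list went against the others were chosen after their values were seen.

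Alternatives were other scalings (RLE factors, library totals), no low-count filter or a stricter one (5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, robust spread, the compared samples alone, a replicate block, leaving out each library, and leaving out immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes. Alternatives added later, with the values in hand, were leaving out X- and Y-linked genes, removing each library's trend with gene length and base composition (spline with 4 degrees of freedom, 10516 genes), leaving out the 50 most abundant genes, limma on log2 RPKM, and leaving Cish out of the SOCS list. In a fit without 1 library the lone sample was assumed to vary like the others. The fits were tested on simulated data with 200 changed genes: edgeR found 94.0% of 2-fold changes ex vivo and 98.5% in vitro, with 8.43% and 3.61% of its calls false. Camera called 0 of 29 unchanged lists. The simulated genes varied independently of each other, so this did not test the preset correlation. A simulated length trend gave 2858 false calls without its removal and 269 with it, beside 169 and 168 of the 200 changed genes found. After removal, false calls thus still outnumbered true ones. The simulated trend was the same in both CIS-null in vitro libraries, whereas the real libraries differed in it. Replicates of each group differed by more than counting error (chi-square per degree of freedom 6.03 to 34.2). No sample was left out of the comparisons. Results for certain genes that the naming rule allows are not reported here.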

Results

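RNA from natural killer (NK) cells of C57BL/6 mice was sequenced in 8 libraries, 2 in each of 4 groups: wild-type and CIS-null cells ex vivo, and wild-type and CIS-null cells in vitro. NK cells are innate lymphocytes that kill infected and transformed cells and secrete cytokines. CIS, the product of Cish, belongs to the SOCS family of intracellular inhibitors of cytokine signalling, and the series concerns its action as a checkpoint in NK cells. The cells had been enriched from spleen, bone marrow and blood with microbeads against CD49b, the antigen of the DX5 antibody. Each library held between 21.5 and 28.1 M (1e6) counts over genes. The wild-type ex vivo libraries held 23.1 and 24.6 M and the CIS-null ex vivo libraries 21.5 and 24.9 M. In vitro the wild-type libraries held 28.1 and 27.9 M and the CIS-null libraries 27.4 and 27.2 M. A total of 13184 genes had enough counts to be tested. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. They also give no culture medium, cytokine or duration for the in vitro cells.

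Cish was lower in every CIS-null library than in every wild-type library of the same state. Ex vivo the wild-type libraries held 9.26 and 9.12 normalised counts per M (CPM), and the CIS-null libraries 1.29 and 2.64 CPM. In vitro the wild-type libraries held 219.8 and 201.9 CPM, and the CIS-null libraries 21.2 and 17.2 CPM. The log2 fold change between genotypes was -2.20 ex vivo (SE 0.250, n = 2 per group, edgeR adjusted p = 0.0315) and -3.46 in vitro (SE 0.193, n = 2 per group, edgeR adjusted p = 9.59e-05). Cish rose on culture in wild-type cells by a log2 fold change of 4.52 (SE 0.206, edgeR adjusted p = 8.87e-07) and in CIS-null cells by 3.26 (SE 0.240, edgeR adjusted p = 7.28e-06). The genotype difference was not shown to differ between the states (log2 difference -1.26, SE 0.322, edgeR adjusted p = 0.117), although it passed by DESeq2 (-1.22, adjusted p = 0.0033) and without CIS-null ex vivo replicate 1 (0.0283). Cish spans positions 107296659 to 107302784 of chromosome 9 in GRCm38. The ex vivo call was lost without either wild-type ex vivo library (adjusted p = 0.283 and 0.299), either wild-type in vitro library (0.0634 and 0.0734) or either CIS-null in vitro library (0.107 and 0.110), while the in vitro call was kept in all 8 fits that left out a library. The ex vivo call was also lost by limma-voom (0.0629), with the compared samples alone (0.242), with a replicate block (0.0562) and by limma on log2 RPKM (0.201).

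**Figure D1:**
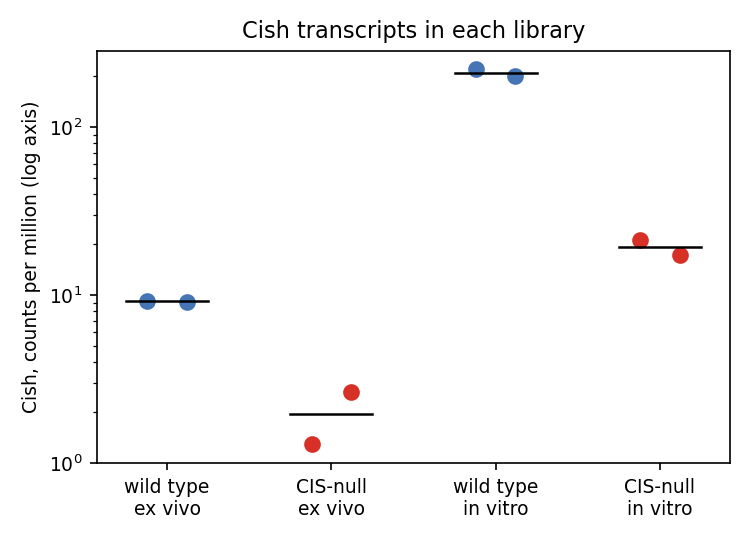
Normalised Cish counts per M (log axis) in each of the 8 libraries, as points, with a line at the mean of the 2 libraries of each group. The CIS-null libraries lie at 1.29 and 2.64 CPM ex vivo and at 21.2 and 17.2 CPM in vitro, below 9.12 and 201.9 CPM, the lower wild-type library of each state.

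The sex-linked transcripts did not follow genotype alone. Xist, the non-coding RNA of the inactive X chromosome, reached 119.6 and 162.1 CPM in the wild-type ex vivo libraries and 130.7 and 89.7 CPM in the CIS-null in vitro libraries. It lay at 0.320 CPM or below in the other 4 libraries. The Y-linked gene Eif2s3y lay at 135.2 and 122.0 CPM in the wild-type in vitro libraries, against 0.0400 and 0 CPM in the CIS-null in vitro libraries. Ex vivo it lay at 34.1 and 21.7 CPM in wild-type cells and at 84.9 and 70.4 CPM in CIS-null cells, and Uty and Kdm5d followed the same order of groups. Ddx3y was also lower in wild-type than in CIS-null cells ex vivo and at 0.0400 CPM or below in CIS-null cells in vitro, but CIS-null ex vivo (67.4 and 110.5 CPM) and wild-type in vitro libraries (79.3 and 82.5 CPM) overlapped. In vitro, therefore, genotype and sex-linked expression separated the libraries in the same way. Ex vivo they did so too, in the reverse order, so neither genotype comparison is free of sex-linked differences. The wild-type ex vivo libraries held both Xist and Y-linked transcripts, the latter at 0.303 to 0.426 of the CIS-null ex vivo level.

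**Figure D2:**
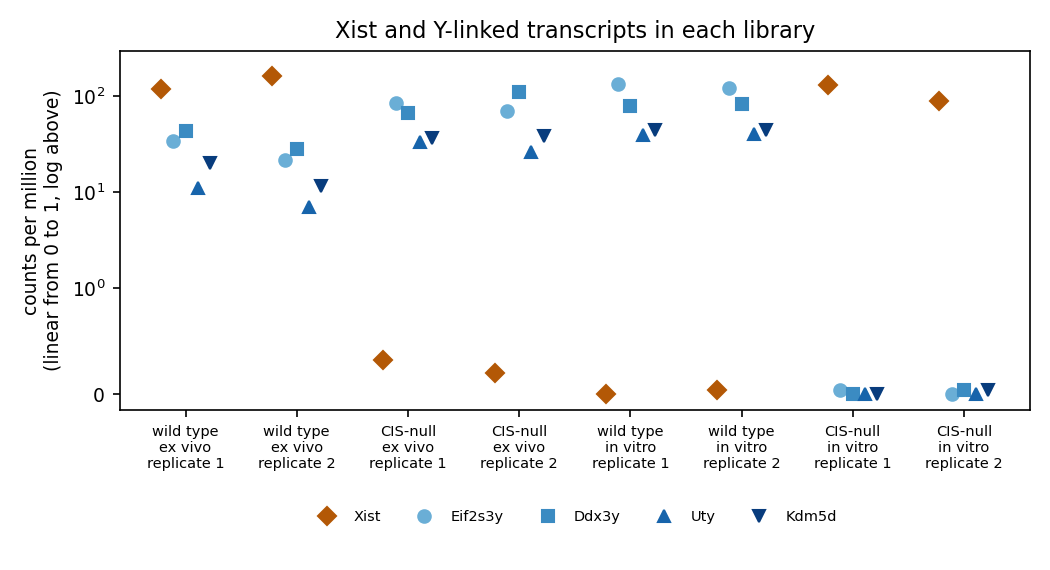
Counts per M of Xist and of the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d in each of the 8 libraries, on an axis that is linear from 0 to 1 and logarithmic above. Xist reaches 119.6 and 162.1 CPM in wild-type ex vivo cells and 130.7 and 89.7 CPM in CIS-null in vitro cells, and the Y-linked genes lie at 0.0400 CPM or below only in the CIS-null in vitro libraries.

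The libraries separated first by culture. The first principal component of log2 CPM held 86.9% of the variance and divided ex vivo from in vitro libraries, and the next held 6.05%. CIS-null ex vivo replicate 1 stood apart on the component after that (score 32.2, 2.20% of the variance), and its ribosomal protein genes took 1.96% of counts, against 1.36% in replicate 2. CIS-null ex vivo replicate 2 stood apart on the component that followed (score 31.9, 1.78% of the variance). Across genes, log ratios fell with gene length, with a Spearman correlation of -0.380 for the ex vivo genotype comparison and -0.534 for the in vitro one over 10516 genes. Between replicates of a group the same correlation was -0.452 in CIS-null ex vivo cells and 0.534 in CIS-null in vitro cells, but -0.133 and 0.0269 in the wild-type groups. Genes are not independent replicates, so these correlations carry no p-value.

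Does loss of CIS change the transcripts of NK cells taken directly from the animal? Ex vivo, 4 genes rose and 4 fell in CIS-null cells. Xist and the Y-linked genes also separated these libraries, so this comparison by itself cannot tell loss of CIS from sex. Gnaz, which encodes a G protein alpha subunit, rose from 0.325 to 11.5 CPM (log2 fold change 5.12, SE 0.309, n = 2 per group, edgeR adjusted p = 0.000433). Cxcr6, a chemokine receptor of tissue-resident lymphocytes, rose from 6.52 to 24 CPM (1.88, SE 0.216, edgeR adjusted p = 0.0315). Sdc4, a heparan sulphate proteoglycan of the cell surface, rose from 27.8 to 65.1 CPM (1.23, SE 0.136, edgeR adjusted p = 0.0315), and Tmem158 rose from 2.87 to 9.09 CPM (1.66, SE 0.205, edgeR adjusted p = 0.0468). Besides Cish, the genes that fell were Xist (-9.08, SE 0.363, edgeR adjusted p = 4.24e-05), Rpl29, a protein of the large ribosomal subunit (136.8 to 3.79 CPM, -5.18, SE 0.313, edgeR adjusted p = 0.000433) and the pseudogene Tmem181b-ps (-1.5, SE 0.163, edgeR adjusted p = 0.0315). Rpl29 and Tmem181b-ps have near-identical copies elsewhere in the genome that could share their reads, and their values are uncertain for that reason.

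The genes next in order did not pass by edgeR. Among higher values were Uty (log2 fold change 1.72, edgeR adjusted p = 0.0748), Eif2s3y (1.48, adjusted p = 0.0713), Tnfsf4, the ligand of OX40 (1.65, adjusted p = 0.0748), and Tle1, a transcriptional corepressor (1.19, adjusted p = 0.124). Without CIS-null ex vivo replicate 2 both Y-linked genes passed (adjusted p = 0.0392 for each), and so did Uty by limma-voom (0.0313) and Eif2s3y with a replicate block (0.0302) or the length trend removed (0.0451). Among lower values were Ptprv (-2.83, adjusted p = 0.0713), Igkv15-103 (-3.77, adjusted p = 0.0713) and the lysosomal galactosidase gene Glb1 (-0.97, adjusted p = 0.0748). Glb1 passed without CIS-null ex vivo replicate 1 (adjusted p = 0.00862) or replicate 2 (0.0392). With the length trend removed Glb1 (0.0377), Ptprv (0.0451) and Igkv15-103 (0.0451) passed, and Igkv15-103 also did by limma-voom (0.0262). Igkv4-61, an immunoglobulin segment of B cells, had 2 counts over both CIS-null libraries and 207 over both wild-type libraries, a ratio of 99.3 (counting interval 27.2 to 826, edgeR adjusted p = 0.0748). Ighg3 had 2 counts in wild-type and 100 in CIS-null cells, a ratio of 52.1 in the other direction (counting interval 14.0 to 436, edgeR adjusted p = 0.0748). DESeq2 called Uty (adjusted p = 1.18e-09), Eif2s3y (1.93e-09), Tnfsf4 (0.00278), Ptprv (0.00431), Igkv15-103 (6.03e-05), Glb1 (8.51e-07) and Ighg3 (0.00565). Without the low-count filter these 7 passed in edgeR as well (0.0109, 0.0109, 0.033, 0.022, 0.0109, 0.0142 and 0.025), as did Igkv4-61 (0.0109).

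The 8 calls compare with 844 genes at an unadjusted p under 0.05, and with 40 calls by DESeq2, which kept all 8, and 7 by limma-voom, which kept 5 of the 8 and lost Cish, Cxcr6 (adjusted p = 0.0657) and Tmem158 (0.0629). Xist, Rpl29 and Gnaz kept their calls in all 8 fits that left out a library. The others lost theirs without wild-type ex vivo replicate 1 (adjusted p = 0.411 for Cxcr6 and Sdc4, 0.483 for Tmem158, 0.242 for Tmem181b-ps) or replicate 2 (0.299 for Cxcr6, Sdc4 and Tmem181b-ps, 0.324 for Tmem158). Without either CIS-null in vitro library Cxcr6 (0.144 and 0.145), Tmem158 (0.107 and 0.114) and Tmem181b-ps (0.107 and 0.110) were lost too, and without either wild-type in vitro library Sdc4 (0.0634 and 0.0734), Tmem158 (0.0828 and 0.0734) and Tmem181b-ps (0.0556 and 0.0558). Without CIS-null ex vivo replicate 1, Cxcr6 (0.0531), Sdc4 (0.0558) and Tmem181b-ps (0.0531) did not pass, and without replicate 2 Tmem158 did not (0.0508). On log2 RPKM Cxcr6 (0.0896), Sdc4 (0.111), Tmem158 (0.0719), Tmem181b-ps (0.0613) and Gnaz (0.0587) did not pass. With a replicate block Sdc4 and Tmem181b-ps (0.0543 each) were lost, and with the compared samples alone Sdc4 (0.0602), Tmem158 and Tmem181b-ps (0.171 each). Tmem158 also lost its call with RLE factors (0.0545), a stricter filter (0.0583), no X- and Y-linked genes (0.0534) and no 50 most abundant genes (0.0533). The count ran from 3 calls without either wild-type ex vivo library to 41 without CIS-null ex vivo replicate 2.

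Among the gene lists, markers of other cell types moved most ex vivo. Basophil and mast cell markers were higher in CIS-null cells than other genes were (camera adjusted p = 1.92e-16, or adjusted p = 0.270 with an estimated correlation). None of the 13 measured members passed over all genes, and 10 passed as higher when adjusted over the list alone. Mcpt8, a basophil protease, went from 0.689 to 2.67 CPM (log2 fold change 1.92, SE 0.451, edgeR adjusted p = 0.472), and DESeq2 called it (adjusted p = 0.00111). Monocyte and macrophage markers (20 measured, camera adjusted p = 0.0134), B cell markers (20 measured, adjusted p = 0.0242) and dendritic cell markers (8 measured, adjusted p = 0.0449) were also higher, with 0 members passing over all genes in each. Adjusted over the list alone, 1 dendritic cell marker passed as higher, 1 monocyte marker as lower and 0 B cell markers. With an estimated correlation these lists had adjusted p = 0.744, 0.744 and 0.541. Neutrophil and granulocyte precursor markers were lower (9 measured, 0 passing over all genes and 1 adjusted over the list alone, camera adjusted p = 0.00489, adjusted p = 0.270 with an estimated correlation).

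These marker lists did not move evenly over the libraries. The summed B cell markers were 625.5 and 500.2 CPM in wild-type cells, against 1125 CPM in CIS-null replicate 1 and 405.4 CPM in CIS-null replicate 2. Monocyte markers were 323.8 and 221.3 CPM in wild-type cells and 450.9 and 298.8 CPM in CIS-null cells. Without CIS-null ex vivo replicate 1 the B cell list was lower instead (camera adjusted p = 1.92e-09), the monocyte list no longer passed (0.414) and neither did the dendritic cell list (0.151). Without wild-type ex vivo replicate 2 none of the 3 passed (0.254, 0.636 and 0.0869), and the dendritic cell list was lost in each of the 6 other such fits as well (0.244 to 0.759).

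Ex vivo, interferon-stimulated genes were lower in CIS-null cells as a list (28 measured, median log2 fold change -0.17, camera adjusted p = 4.08e-05, adjusted p = 0.270 with an estimated correlation). So were G2/M and mitosis genes (30 measured, median -0.15, camera adjusted p = 0.00489, adjusted p = 0.744 with an estimated correlation). No member of either list passed over all genes or adjusted over the list alone. The direction of the G2/M list turned without CIS-null ex vivo replicate 1 (camera adjusted p = 4.75e-05, higher), and the call was lost without wild-type ex vivo replicate 2 (0.170). Its summed level was 305.3 and 345.0 CPM in wild-type cells and 188.7 and 362.5 CPM in CIS-null cells. The SOCS family was lower (8 measured, camera adjusted p = 0.00306, adjusted p = 0.270 with an estimated correlation), with Cish as its only member passing over all genes or adjusted over the list alone. Without Cish the other 7 did not pass as a list (camera adjusted p = 0.6). Oxidative phosphorylation genes were higher (28 measured, 0 passing either way, median 0.15, camera adjusted p = 0.00306, adjusted p = 0.744 with an estimated correlation). That call was lost without CIS-null ex vivo replicate 1 (0.491) and with the length trend removed (0.299). Among markers of type 1 and type 2 innate lymphoid cells, Cxcr6 was the only 1 of 12 measured members to rise, over all genes or over the list alone (camera adjusted p = 0.00892, adjusted p = 0.374 with an estimated correlation). This list no longer passed without wild-type ex vivo replicate 1 (0.190) or CIS-null ex vivo replicate 2 (0.416).

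The lists of NK function did not pass ex vivo. Cytotoxic granule genes and death ligands had a median of 0.09 and a mean of -0.02 (camera adjusted p = 0.0861), and the camera adjusted p was also 0.0861 for mature NK markers and for NK cytokines. Activating receptors had an adjusted p of 0.0992 and inhibitory receptors 0.148. Over all genes, 0 members of these 5 lists passed, and adjusted over the list alone 1 mature NK marker did, as higher. By fry, which tests each list's own genes without comparing them with others, 0 of 30 lists passed ex vivo.

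How does loss of CIS change NK cells in culture? In vitro, 1445 genes rose and 1929 fell in CIS-null cells, 25.6% of those tested. Of these, 233 rose and 425 fell at least 2-fold. Among the genes that rose were Gzmb, Cd3e and the amino acid transporter Slc7a5, and among those that fell were Mki67 and Eomes. The comparison also separated the libraries by Xist and the Y-linked genes, and 73 of the calls lay on the X chromosome and 4 on the Y chromosome. The lower genes were longer, with a median of 4710 bases, against 1686 bases for the higher genes and 2682.5 bases for all tested genes. Unadjusted, 5292 genes had a p under 0.05, and DESeq2 called 3603 genes and limma-voom 3614.

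The split between higher and lower genes depended on the scaling. It was 42.8% higher with the trimmed mean of M values, 21.2% (744 higher, 2773 lower) with library totals, which moved the median of all genes to -0.13, and 55.4% (1630 higher, 1314 lower) with the trend in gene length and base composition removed. The count changed with the library left out. It fell to 500 without CIS-null in vitro replicate 2, of which 496 were among the original calls in the same direction, to 868 without wild-type in vitro replicate 1 and to 1113 without wild-type in vitro replicate 2. Without wild-type ex vivo replicate 1 or replicate 2 it was 1901 and 1879, without CIS-null ex vivo replicate 1 or replicate 2 it rose to 4296 and 4287, and without CIS-null in vitro replicate 1 to 3717. Of 3374 calls, 2073 were kept in the same direction with the trend removed.

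T cell receptor and CD3 transcripts were among the genes that rose in vitro. Of 19 measured T cell markers, 10 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.16e-09, adjusted p = 0.620 with an estimated correlation). Cd3e went from 6.69 to 77.7 CPM (log2 fold change 3.54, SE 0.377, n = 2 per group, edgeR adjusted p = 0.00297), Cd3d from 19.3 to 256.5 CPM (3.73, SE 0.509, edgeR adjusted p = 0.00457) and Cd3g from 138.8 to 472.9 CPM (1.77, SE 0.183, edgeR adjusted p = 0.00290). These genes encode the signalling chains of the T cell receptor complex. The gamma chain constant segments Tcrg-C2 (5.65 to 79.7 CPM, 3.82, edgeR adjusted p = 0.00200) and Tcrg-C4 (5.72 to 66.0 CPM, 3.53, adjusted p = 0.00409) rose with them. So did Trgv2 (4.06, adjusted p = 0.00200), Tcrg-V4 (3.81, adjusted p = 0.00136), Trgj2 (3.8, adjusted p = 0.00293) and the beta segment Trbd2 (3.85, adjusted p = 0.00422). Trbv12-2 (4.04, adjusted p = 0.00945) and Trav13-4-dv7 (3.63, adjusted p = 0.0186) lost their calls without CIS-null in vitro replicate 2 (adjusted p = 0.0730 and 0.115), and Trav13-4-dv7 also without CIS-null in vitro replicate 1 (0.0582) or wild-type in vitro replicate 2 (0.0891). The delta constant gene Trdc, at 130.1 CPM in wild-type cells, rose less (0.88, adjusted p = 0.00362). On log2 RPKM Trbd2 (0.0572) and Trav13-4-dv7 (0.132) did not pass. Receptor segments resemble each other, so their single values are uncertain. Without CIS-null in vitro replicate 2, 6 members of the list passed.

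Beside these, the largest increases among genes of at least 5 CPM with non-overlapping libraries included Xist (ratio 6330, counting interval 1140 to 250000) and Crisp1, a cysteine-rich secretory protein (3.49, SE 0.478, edgeR adjusted p = 0.00654). The largest decreases were Y-linked: Uty was at least 673-fold lower, against a floor of 3 counts over the group, and Eif2s3y, Ddx3y and Kdm5d had 1 count each over both CIS-null libraries, ratios of 6550 (counting interval 1180 to 259000), 4120 (739 to 163000) and 2270 (408 to 89800). Rpl29 fell from 196.1 to 1.98 CPM (-6.62, SE 0.339, edgeR adjusted p = 7.73e-05), and Wdfy1 from 52.1 to 7.43 CPM (-2.81, SE 0.180, edgeR adjusted p = 0.000262). Further decreases were in Dscam, a cell adhesion receptor (-2.40, edgeR adjusted p = 0.00123), Ccdc88a (-2.12, adjusted p = 0.00521), Atp10d (-2.23, adjusted p = 0.0186) and Ttn (-2.20, adjusted p = 0.00508). Atp10d lost its call without CIS-null in vitro replicate 2 (adjusted p = 0.154) or wild-type in vitro replicate 2 (0.0969), by limma-voom (0.0541) and on log2 RPKM (0.0558), and Ttn without CIS-null in vitro replicate 2 (0.0505) and with the length trend removed (0.303).

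Cytotoxic granule genes were higher as a list in cultured CIS-null cells. Of 25 measured members, which include death ligands, 13 rose and 0 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.68e-06, adjusted p = 0.505 with an estimated correlation). Gzmb, the granzyme that cleaves caspases in target cells, went from 11570 to 24560 CPM (log2 fold change 1.09, SE 0.115, n = 2 per group, edgeR adjusted p = 0.00297). Serpinb9, an inhibitor of granzyme B, rose by 1.14 (SE 0.106, edgeR adjusted p = 0.00200) and Serpinb9b by 2.21 (SE 0.280, edgeR adjusted p = 0.00381). Gzme rose by 2.42 (adjusted p = 0.00850), Gzma by 0.85 (adjusted p = 0.00830) and the perforin gene Prf1 by 0.62 (adjusted p = 0.00930). Granzymes are a family of close paralogs, which makes single members uncertain. Granzyme genes together took 3.95% and 3.99% of counts in the wild-type libraries and 6.28% and 7.24% in the CIS-null libraries. Gzma lost its call without wild-type in vitro replicate 2 (0.0521) or CIS-null in vitro replicate 2 (0.0537), and Prf1 without the former (0.0627). The list had 5 and 7 members passing in those fits. On the deposited log2 RPKM values Gzmb (log2 fold change 0.13, limma adjusted p = 0.744), Gzma (0, adjusted p = 1) and Prf1 (0.38, adjusted p = 0.0877) did not pass, while Serpinb9, Serpinb9b and Gzme did.

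Secreted factors and receptors changed alongside. Of 15 NK cytokines and chemokines, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.620 with an estimated correlation). Ccl1, a chemokine that acts on CCR8, rose by 0.95 (SE 0.106, edgeR adjusted p = 0.00302), Xcl1, which attracts dendritic cells, by 0.55 (SE 0.101, edgeR adjusted p = 0.00931) and Ifng, the interferon gamma gene, by 0.79 (SE 0.175, edgeR adjusted p = 0.0154). The member that fell was Ltb (-0.75, adjusted p = 0.0399). Ifng lost its call without wild-type in vitro replicate 1 (0.0881) or CIS-null in vitro replicate 1 (0.0574), Xcl1 without wild-type in vitro replicate 1 (0.0543) or CIS-null in vitro replicate 2 (0.0561), and Ltb without either wild-type ex vivo library (0.0751 and 0.0764), wild-type in vitro replicate 2 (0.246) or either CIS-null in vitro library (0.0937 and 0.220). The list was lost without CIS-null in vitro replicate 1 (0.151) and with the length trend removed (0.931), where 1 member rose and 1 fell and neither Ifng (0.190) nor Xcl1 (0.813) passed. On log2 RPKM Ccl1 (0.219), Xcl1 (0.057), Ifng (0.0532) and Ltb (0.0897) did not pass, nor did Ltb with a replicate block (0.0644).

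Among 24 inhibitory receptors and checkpoints, 10 rose and 2 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00362, adjusted p = 0.686 with an estimated correlation). The Ly49 receptors Klra5 (log2 fold change 0.90, SE 0.126, edgeR adjusted p = 0.00473) and Klra1 (1.36, SE 0.268, edgeR adjusted p = 0.0109) rose, while Klra3 (-0.71, adjusted p = 0.0128) and Klra10 (-0.69, adjusted p = 0.0420) fell. These receptors are close paralogs and could exchange reads. Klrg1, an inhibitory receptor of mature NK cells, missed the threshold (0.78, adjusted p = 0.0509). It passed by DESeq2 (0.00273), limma-voom (0.0396), RLE factors (0.046), no low-count filter (0.0309), a stricter filter (0.0446) and robust spread (0.0482). It also did without the 50 most abundant genes (0.0455), without immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes (0.0458), and without either CIS-null ex vivo library (0.0386 and 0.0393) or wild-type in vitro replicate 1 (0.0185). Without CIS-null in vitro replicate 2, Klra1 (0.0857), Klra3 (0.0505) and Klra10 (0.0938) did not pass and 1 member of the list did. Klra3 also lost its call without wild-type in vitro replicate 1 (0.0539) or replicate 2 (0.0762), and Klra10 without either wild-type ex vivo library (0.0814 and 0.0820), wild-type in vitro replicate 1 (0.266) or CIS-null in vitro replicate 1 (0.149). Klra10 did not pass by DESeq2 (0.0661) or limma-voom (0.064), without the filter (0.0563), with the compared samples alone (0.0956), with a replicate block (0.0702) or on log2 RPKM (0.0687). The list did not pass with the length trend removed (0.949). Of 27 activating receptors and adaptors, 3 rose and 2 fell over all genes and over the list alone (camera adjusted p = 0.853). They included the costimulatory receptor Tnfrsf9 (0.72, SE 0.106, edgeR adjusted p = 0.00541) as higher and Klrb1f (-1.04, SE 0.0899, edgeR adjusted p = 0.00171) as lower. With the length trend removed 4 activating receptors and adaptors rose and 7 fell, and the list did not pass (camera adjusted p = 0.0902).

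Genes of amino acid uptake and the ATF4 response rose in cultured CIS-null cells. Of 20 measured members of that list, 15 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 1.31e-06, adjusted p = 0.505 with an estimated correlation). Slc7a5, the large neutral amino acid transporter, went from 74.4 to 134.2 CPM (log2 fold change 0.85, SE 0.119, n = 2 per group, edgeR adjusted p = 0.00473). Atf4, the transcription factor of the amino acid response, rose by 0.70 (SE 0.107, edgeR adjusted p = 0.00569) and asparagine synthetase, Asns, by 1.5 (SE 0.234, edgeR adjusted p = 0.00603). Sesn2, which restrains mTORC1, was the member that fell (-0.42, adjusted p = 0.0448). Asns lost its call without CIS-null in vitro replicate 2 (0.0574), where 2 members of the list passed. Sesn2 lost its call without either wild-type ex vivo library (0.0886 and 0.0906), wild-type in vitro replicate 1 (0.306) or either CIS-null in vitro library (0.0630 and 0.227), and with the length trend removed (0.140). It did not pass by DESeq2 (0.0731), with RLE factors (0.0518), without the filter (0.0703), with the compared samples alone (0.0774), with a replicate block (0.0554), without the 50 most abundant genes (0.053) or on log2 RPKM (0.105), where Asns did not either (0.0798).

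Of 20 glycolysis genes, 7 rose and 1 fell in vitro, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00158, adjusted p = 0.714 with an estimated correlation). Lactate dehydrogenase A, Ldha, rose by 0.76 (SE 0.126, edgeR adjusted p = 0.00654) and the lactate transporter Slc16a1 by 0.94 (SE 0.130, edgeR adjusted p = 0.00460), while hexokinase 1, Hk1, fell by 0.68 (SE 0.135, edgeR adjusted p = 0.0112). The glucose transporter Slc2a1 did not pass (0.51, adjusted p = 0.124), but did by DESeq2 (0.0411) and without wild-type in vitro replicate 2 (0.0142). Hk1 lost its call without CIS-null in vitro replicate 2 (0.0681) and without either wild-type in vitro library (0.0654 and 0.0575), and the list lost its own without wild-type in vitro replicate 1 (0.0570). Of 28 oxidative phosphorylation genes, 14 rose and 0 fell, or 21 and 0 adjusted over the list alone (camera adjusted p = 2.92e-05, adjusted p = 0.754 with an estimated correlation). Atp5b, a subunit of ATP synthase, went from 1397 to 1847 CPM (0.40, SE 0.0980, edgeR adjusted p = 0.0212). With library totals as the scaling, 0 of these 28 passed, and with the length trend removed 3 rose and 2 fell and the list did not pass (0.646). Their number was also 0 without either wild-type library of each state or without CIS-null in vitro replicate 2, where Atp5b had adjusted p = 0.0582, 0.0602, 0.0935, 0.0860 and 0.106. Atp5b did not pass with library totals (0.0669) or on log2 RPKM (0.289).

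Mitotic genes fell in cultured CIS-null cells. Of 30 measured G2/M genes, 11 fell and 0 rose, or 13 and 0 adjusted over the list alone (camera adjusted p = 0.000238, adjusted p = 0.885 with an estimated correlation). The proliferation marker Mki67 fell from 102.9 to 23.3 CPM (log2 fold change -2.15, SE 0.412, n = 2 per group, edgeR adjusted p = 0.01) and the kinetochore gene Cenpf from 17.8 to 4.34 CPM (-2.03, SE 0.305, edgeR adjusted p = 0.00554). Of 31 S phase and DNA replication genes, 2 rose and 2 fell, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.731). The summed G2/M level was 2325 and 2221 CPM in wild-type cells and 1569 and 1650 CPM in CIS-null cells. Without CIS-null in vitro replicate 2, 0 G2/M members passed over all genes (Mki67 adjusted p = 0.0941, Cenpf 0.0574) although the list still did, and without wild-type in vitro replicate 1 only 1 member passed (Mki67 0.0598). On log2 RPKM Mki67 had adjusted p = 0.0504.

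NK transcription factors fell as a list in vitro: of 28 measured, 12 fell and 2 rose, or 16 and 4 adjusted over the list alone (camera adjusted p = 0.00240, adjusted p = 0.714 with an estimated correlation). Eomes, a T-box factor of the NK lineage, fell from 174.4 to 117.0 CPM (log2 fold change -0.58, SE 0.109, edgeR adjusted p = 0.00958). Zeb2, a factor of terminal maturation, fell from 15.5 to 7.04 CPM (-1.13, adjusted p = 0.0130). Irf8 rose (0.63, adjusted p = 0.0464), but did not pass on log2 RPKM (limma adjusted p = 0.131). Id3 had 2 counts in wild-type and 49 in CIS-null cells (ratio 27.5, counting interval 7.23 to 234, adjusted p = 0.00657). Of 22 components of the IL-15 receptor and JAK-STAT pathway, 8 fell and 0 rose, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.0217, adjusted p = 0.930 with an estimated correlation). They included the kinase genes Jak1 (-0.58, adjusted p = 0.0168), Tyk2 (-0.57, adjusted p = 0.0156) and Mtor (-0.71, adjusted p = 0.0103) and the transcription factor Stat4 (-0.68, adjusted p = 0.0112). Without CIS-null in vitro replicate 2 none of these genes passed, with adjusted p = 0.0692 for Eomes, 0.109 for Zeb2, 0.132 for Irf8, 0.0548 for Id3, 0.0880 for Jak1, 0.0746 for Tyk2, 0.0757 for Mtor and 0.0878 for Stat4. Without wild-type in vitro replicate 1 the same held for Eomes (0.0738), Zeb2 (0.0817), Irf8 (0.128), Jak1 (0.101), Tyk2 (0.0987), Mtor (0.0564) and Stat4 (0.0776), and without wild-type in vitro replicate 2 for Irf8 (0.185), Jak1 (0.0625), Tyk2 (0.0615) and Mtor (0.0588). Irf8 was lost as well without either wild-type ex vivo library (0.0889 and 0.0895) or CIS-null in vitro replicate 1 (0.158), with library totals (0.104) and with a replicate block (0.0671). The JAK-STAT list was also lost without CIS-null in vitro replicate 2 (0.218) or wild-type in vitro replicate 1 (0.0944), and with the length trend removed 2 members rose, 1 fell and the list did not pass (0.962), nor did Jak1 (0.0526), Tyk2 (0.131) or Mtor (0.647).

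Of 15 mature NK markers in vitro, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone. Their median was -0.09, or 0.27 without 1 member at the floor, and their mean 0.12, and the test found them higher (camera adjusted p = 0.0148, adjusted p = 0.686 with an estimated correlation, 0.0627 without wild-type in vitro replicate 1). Ly6c2, a surface marker of matured lymphocytes, rose from 27.9 to 109.3 CPM (log2 fold change 1.97, SE 0.157, n = 2 per group, edgeR adjusted p = 0.00124). Of 18 immature NK markers, 3 rose and 3 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.732), and the receptor gene Kit fell from 851.4 to 392.1 CPM (-1.12, SE 0.164, edgeR adjusted p = 0.00528), a call lost without CIS-null in vitro replicate 2 (0.0509). The SOCS family was lower (8 measured, 0 higher and 2 lower over all genes and over the list alone, camera adjusted p = 0.0101, adjusted p = 0.505 with an estimated correlation), with Cish and Socs7 (-0.37, adjusted p = 0.0474). Without Cish the other 7 did not pass as a list (camera adjusted p = 0.732). Without wild-type ex vivo replicate 1 or 2, wild-type in vitro replicate 1 or 2, or CIS-null in vitro replicate 2, Socs7 did not pass (0.0969, 0.0977, 0.237, 0.132 and 0.250). Nor did it by DESeq2 (0.052), with RLE factors (0.0593), without the filter (0.0744), with the compared samples alone (0.0665), with a replicate block (0.0783), with the length trend removed (0.119), without the 50 most abundant genes (0.0598) or on log2 RPKM (0.111). STAT5 target genes did not move together (2 higher and 2 lower of 23, 1 and 1 adjusted over the list alone, camera adjusted p = 0.668), with Xbp1 higher (0.61, SE 0.0942, edgeR adjusted p = 0.00574).

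Lists that did not pass in vitro still held called genes. Of 27 cholesterol and fatty acid synthesis genes 7 rose and 2 fell, or 8 and 3 over the list alone (camera adjusted p = 0.1, and 0.000851 with the length trend removed). Of 28 interferon-stimulated genes 2 rose, Oas1a and Usp18, and 6 fell, the same over the list alone (adjusted p = 0.668), with Stat2 lower (log2 fold change -1.06, SE 0.103, edgeR adjusted p = 0.00233). Without CIS-null in vitro replicate 2 neither Oas1a (0.177) nor Usp18 (0.0699) passed, nor did Oas1a without either wild-type ex vivo library (0.0635 and 0.0648) or CIS-null in vitro replicate 1 (0.0555), or on log2 RPKM (0.0573), or Usp18 without wild-type in vitro replicate 2 (0.108) or CIS-null in vitro replicate 1 (0.0647). Of 22 homing genes 1 rose and 3 fell, the same over the list alone (adjusted p = 0.668), with Itga2, which encodes the CD49b chain used for enrichment, lower (-1.20, SE 0.156, edgeR adjusted p = 0.00409). Of 16 BCL2 family genes 3 rose and 2 fell, the same over the list alone (adjusted p = 0.345), with Bcl2a1b higher (1.08, SE 0.120, edgeR adjusted p = 0.00302). Of 12 innate lymphoid cell markers 1 rose and 2 fell, the same over the list alone (adjusted p = 0.853). Of 13 basophil and mast cell markers 2 rose, Mcpt8 (1.51, edgeR adjusted p = 0.00917) and Ifitm1 (1.34, adjusted p = 0.00805), the same over the list alone, and the list did not pass (adjusted p = 0.209). Its summed level was 303.2 and 339.4 CPM in wild-type cells and 628.2 and 894.5 CPM in CIS-null cells. Mcpt8 and Ifitm1 lost their calls without wild-type in vitro replicate 1 (0.0572 and 0.0537) or CIS-null in vitro replicate 2 (0.0777 and 0.0619), and on log2 RPKM (0.0514 and 0.0579). Plasma cell markers had 1 of 10 higher (0.574) and platelet markers 1 of 14 lower (0.668), each the same over the list alone. Monocyte markers had 1 of 20 higher (0.668) and dendritic cell markers 1 of 8 (0.859), with 0 in each over the list alone. B cell (20, adjusted p = 0.856), neutrophil (9, 0.676), erythroid (8, 0.856) and immediate early genes (25, 0.853) had 0 passing either way, and only 1 stromal gene was tested, too few for a list test.

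**Figure D3:**
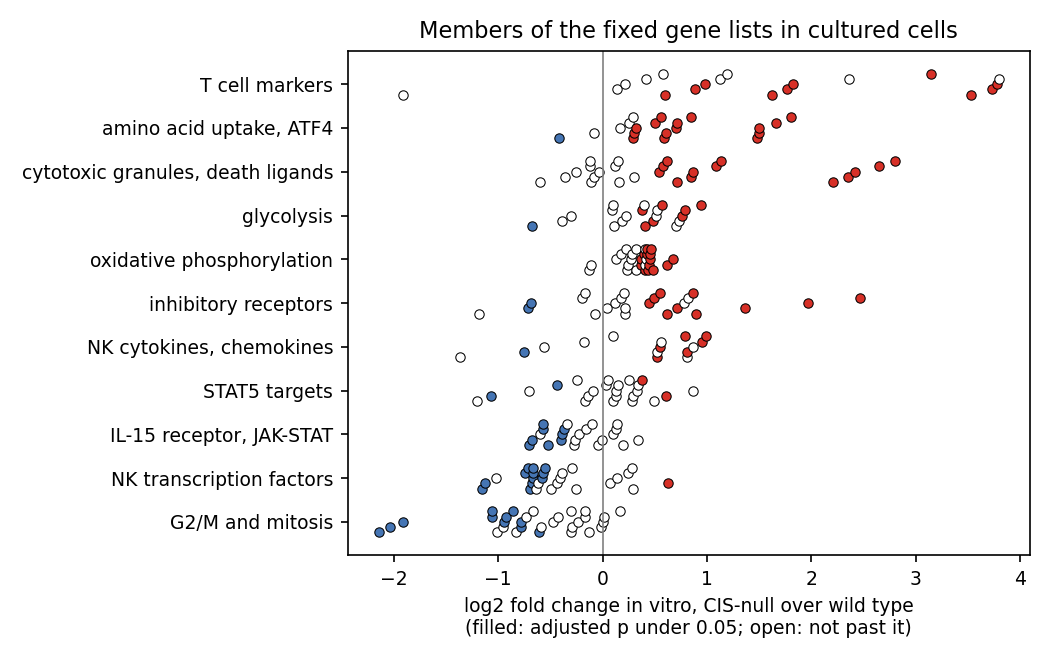
Log2 fold changes in vitro, CIS-null over wild type, of the measured members of 11 gene lists (points, 1 per gene, n = 2 libraries per group), filled where the edgeR adjusted p passed. Members with 3 or fewer counts in a compared group are left out, the vertical spread within a list has no meaning, and the members that passed among T cell markers (10 higher, 0 lower) and G2/M genes (0 higher, 11 lower) lie on opposite sides of 0.

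Did the genotype effect differ between the states? The interaction passed for 18 genes, 7 higher and 11 lower, at 2586 genes with an unadjusted p under 0.05. DESeq2 called 579 genes, limma-voom 17, and limma on the deposited log2 RPKM values 0 (2224 genes at an unadjusted p under 0.05). Xist and the Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty were among them, with 3 of the 18 on the X chromosome and 4 on the Y chromosome. Of the others, Sdc4 rose ex vivo and fell in vitro (log2 difference -2.67, SE 0.192, n = 2 per group, edgeR adjusted p = 0.000915). Cd3g, which rose in vitro, differed between the states (2.39, SE 0.277, edgeR adjusted p = 0.0296). The genotype difference in Xist and the Y-linked genes also turned between the states. For any gene or list, the interaction therefore cannot be told apart from an effect of sex. Gzmb (1.03, adjusted p = 0.0598) and Slc7a5 (1.18, adjusted p = 0.0596) did not pass by edgeR. Both did by DESeq2 (2.72e-08 and 2.35e-06), without the low-count filter (0.0194 each), with the length trend removed (0.0499 and 0.0205) and without CIS-null ex vivo replicate 1 (0.0352 and 0.0262) or CIS-null in vitro replicate 1 (0.0433 and 0.0457). Slc7a5 also passed without the 50 most abundant genes (0.0458) and without immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes (0.0493). Of the 18 genes, 6 were kept in all 8 fits that left out a library, and Sdc4 was the only autosomal one. Cd3g had adjusted p = 0.118 and 0.214 without wild-type ex vivo replicates 1 and 2, 0.0724 without wild-type in vitro replicate 2 and 0.167 without CIS-null in vitro replicate 2, 0.0779 with a replicate block and 0.0665 without X- and Y-linked genes. On log2 RPKM the adjusted p was 0.14 for Cd3g and 0.0559 for Sdc4. The count itself ran from 6, without wild-type ex vivo replicate 2 or CIS-null in vitro replicate 2, to 378, without CIS-null in vitro replicate 1. With library totals, which moved the median of all genes to -0.15, 4 were higher and 14 lower, and with the length trend removed 107 were higher and 102 lower.

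Of the lists that passed, T cell markers had the largest median difference between states (median 0.83, camera adjusted p = 2.51e-10), with Cd3g as the only member passing over all genes and 6 passing as higher over the list alone. Genes of amino acid uptake (median 0.52, adjusted p = 7.99e-09, 8 higher over the list alone), glycolysis (0.28, adjusted p = 0.00109, 3 higher and 1 lower) and oxidative phosphorylation (0.22, adjusted p = 0.00670, 0 passing) were also higher, with 0 members passing over all genes in each. Each of these lists had adjusted p = 0.807 with an estimated correlation. The glycolysis call was lost without wild-type in vitro replicate 1 (0.0659), and the oxidative phosphorylation call without CIS-null ex vivo replicate 2 (0.0896) or CIS-null in vitro replicate 2 (0.171), and with the length trend removed (0.872).

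Few genes passed in the same direction in both genotype comparisons. Higher in both were Cxcr6 and Tmem158, 2 genes where 0.438 would be shared by independent lists of the same sizes. Lower in both were Cish, Rpl29 and Tmem181b-ps, 3 genes against 0.585. In vitro Cxcr6 rose by a log2 fold change of 0.90 (SE 0.183, edgeR adjusted p = 0.0119), Tmem158 by 1.26 (SE 0.201, edgeR adjusted p = 0.00612), and Tmem181b-ps fell by 1.58 (SE 0.161, edgeR adjusted p = 0.00290). Without CIS-null in vitro replicate 2, Cxcr6 (0.0791) and Tmem158 (0.0505) did not pass in vitro, nor did Cxcr6 on log2 RPKM (0.0534). Sdc4 and Xist passed in both comparisons in opposite directions.

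Whether called genes lay near Cish was asked because a targeted allele can carry neighbouring sequence of another strain. Within 10 Mb of Cish, 1 of 162 tested genes passed ex vivo, Rpl29, against 6 of 12685 others with a position (odds ratio 13.1, 95% interval 0.284 to 109, two-sided Fisher's exact p = 0.0850). In vitro 49 of 162 passed, 30.2% against 25.9% of the others (odds ratio 1.24, 95% interval 0.866 to 1.75, two-sided Fisher's exact p = 0.208). Cxcr6 and Tmem158 lie on the same chromosome, within 20 Mb. Over that window the ex vivo odds ratio was 35.4 (5.16 to 210, exact p = 0.000299, 3 of 269 genes), and within 5 Mb the in vitro ratio was 1.5 (1.01 to 2.20, exact p = 0.0397).

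**Figure D4:**
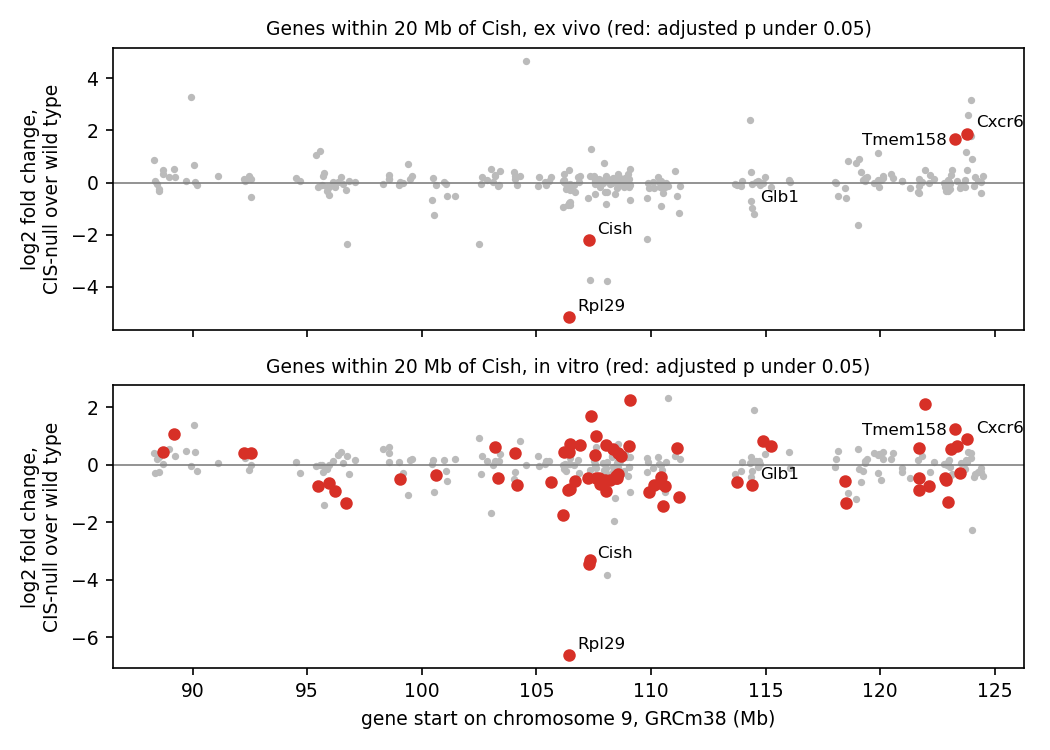
Log2 fold changes (CIS-null over wild type, n = 2 libraries per group) of tested genes within 20 Mb of Cish against their start on chromosome 9 of GRCm38 in Mb, ex vivo above and in vitro below, with red points for genes whose edgeR adjusted p passed. Ex vivo the red points are Cish, Rpl29, Tmem158 and Cxcr6, and in vitro they are Cish and 72 other genes, with Rpl29, Tmem158 and Cxcr6 among them.

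What does culture itself change? In wild-type cells 4229 genes rose and 4166 fell between ex vivo and in vitro libraries, 63.7% of those tested, and 1937 rose and 1963 fell at least 2-fold. Granzyme genes that were close to absent ex vivo reached high levels. Gzmc went from 2.77 to 14030 CPM (log2 fold change 12.30, SE 0.292, n = 2 per group, edgeR adjusted p = 5.34e-08). Gzmd, Gzme and Gzmg, with 0 counts in both wild-type ex vivo libraries, were at least 3630-fold, 1350-fold and 812-fold higher against a floor of 3 counts over the group. The chemokine gene Ccl1 (10.62, SE 0.221, edgeR adjusted p = 5.19e-08) and the aryl hydrocarbon receptor repressor Ahrr (10.59, SE 0.225, edgeR adjusted p = 5.19e-08) rose. With 1 or 2 counts ex vivo, the desmosomal cadherin Dsc2 had a ratio of 2540 (counting interval 456 to 1e+05), AA467197 of 2690 (483 to 106000), the metallothionein Mt2 of 2340 (419 to 92300) and Zmat4 of 909 (251 to 7510).

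Receptors of circulating mature NK cells were among the genes that fell on culture. S1pr5, the sphingosine phosphate receptor through which NK cells leave tissues, fell from 536.2 to 0.245 CPM (log2 fold change -11.07, SE 0.245, n = 2 per group, edgeR adjusted p = 5.19e-08), and the fractalkine receptor Cx3cr1 from 176.0 to 0.0876 CPM (-10.90, SE 0.708, edgeR adjusted p = 5.31e-06). As3mt, an arsenic methyltransferase, fell by 10.74 on the log2 scale (SE 0.247, edgeR adjusted p = 5.19e-08). Cdh22 and Nhsl2, with 0 counts in culture, were at least 719-fold and 671-fold lower. Genes typical of macrophages and B cells were as strongly lower: Vcam1 at least 801-fold, Igkc, the kappa light chain, at least 1640-fold, Csf1r by a ratio of 2350 (counting interval 422 to 93000) and the iron exporter Slc40a1 by 3160 (567 to 125000). Xist differed by a ratio of 8100 (1450 to 320000), in step with the sex-linked difference between these groups. Culture and sex-linked expression thus separated the wild-type libraries in the same way, so single genes cannot be assigned to culture alone.

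Cholesterol synthesis and proliferation genes rose together. Of 27 genes of cholesterol and fatty acid synthesis, 23 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 1.40e-25, adjusted p = 0.0594 with an estimated correlation). Squalene epoxidase, Sqle, rose from 2.62 to 107.9 CPM (log2 fold change 5.36, SE 0.121, edgeR adjusted p = 5.19e-08). Acly was the member that fell. All 30 measured G2/M genes rose, over all genes and over the list alone (camera adjusted p = 1.08e-18, adjusted p = 0.294 with an estimated correlation), with the cyclin gene Ccnb1 at 3.67 and Cdk1 at 3.42. Of 31 S phase genes 27 rose and 1 fell, Cdt1, or 28 and 1 adjusted over the list alone (camera adjusted p = 1.92e-10, adjusted p = 0.341 with an estimated correlation), with thymidine kinase, Tk1, at 3.09. Of 20 glycolysis genes 13 rose and 1 fell, Pfkp, the same over the list alone (camera adjusted p = 8.63e-05, adjusted p = 0.398 with an estimated correlation), with hexokinase 2, Hk2, at 4.38. Of 20 amino acid uptake genes 10 rose and 2 fell, Slc3a2 and Ddit3, the same over the list alone (camera adjusted p = 0.0139, adjusted p = 0.398 with an estimated correlation), with Asns at 5.86. Of 28 oxidative phosphorylation genes 20 rose and 2 fell, Ndufa4 and Sdha, or 22 and 2 over the list alone (camera adjusted p = 0.0142, adjusted p = 0.634 with an estimated correlation, 0.837 with the length trend removed). With that trend removed 9 of them rose and 4 fell.

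The NK programme shifted with culture. Of 15 mature NK markers 12 fell and 2 rose, Gzma and Gzmb, the same over the list alone (camera adjusted p = 1.43e-12, adjusted p = 0.0850 with an estimated correlation), among them the chymase gene Cma1 (log2 fold change -9.65, SE 0.310, edgeR adjusted p = 2.44e-07), Itgam, the CD11b gene (-3.36, SE 0.165, edgeR adjusted p = 1.30e-06) and Ly6c2 (-4.09, SE 0.169, edgeR adjusted p = 5.89e-07). Of 28 NK transcription factors 20 fell and 4 rose, or 21 and 5 over the list alone (camera adjusted p = 5.65e-06, adjusted p = 0.341 with an estimated correlation). Klf2, a factor of lymphocyte quiescence and trafficking, fell from 667.1 to 2.51 CPM (-8.05, SE 0.281, edgeR adjusted p = 3.12e-07), while Zeb2 fell by 3.98 and Eomes by 2 on the log2 scale. The 4 that rose were Nfil3, Irf4, Batf and Bcl11b. Of 22 homing and adhesion genes 16 fell and 5 rose, the same over the list alone (camera adjusted p = 6.01e-06, adjusted p = 0.0850 with an estimated correlation), with Cxcr6 at 5.71. Of 12 markers of type 1 and type 2 innate lymphoid cells 9 rose and 2 fell, Gata3 and Il7r, the same over the list alone (camera adjusted p = 1.04e-07, adjusted p = 0.0850 with an estimated correlation), with the integrin gene Itga1 at 4.86 and Inpp4b at 4.73. Of 25 cytotoxic genes 14 rose and 10 fell, the same over the list alone (camera adjusted p = 0.00119, higher, adjusted p = 0.294 with an estimated correlation), with Gzmb at 3.6 and Gzmm at -3.43.

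Cytokine responses were mixed. Of 23 STAT5 target genes 16 rose and 3 fell, Osm, Ccnd3 and Socs3, or 17 and 4 over the list alone (camera adjusted p = 0.000407, adjusted p = 0.294 with an estimated correlation). Il2ra, the high-affinity interleukin 2 receptor chain, rose by a log2 fold change of 4.67 (SE 0.258, edgeR adjusted p = 2.27e-06) and Socs2 by 2.84 (SE 0.166, edgeR adjusted p = 3.02e-06). Of 15 NK cytokines 9 rose and 4 fell, the same over the list alone (camera adjusted p = 0.00241, adjusted p = 0.281 with an estimated correlation, 0.0649 with the length trend removed), with Xcl1 at 3.76, Tnf at 3.97 and Ccl5 at -2.97. Of 24 inhibitory receptors 9 rose and 10 fell, or 9 and 11 over the list alone. Their median was -0.11 while the test found them higher (camera adjusted p = 0.0139, adjusted p = 0.382 with an estimated correlation, 0.357 with the length trend removed). Lag3 rose by 4.29 and Cd200r1 by 5.78, while Klrg1 fell by 4.4. Of 16 BCL2 family genes 9 rose and 3 fell, Bbc3, Pmaip1 and Bid, the same over the list alone (camera adjusted p = 0.0166, adjusted p = 0.281 with an estimated correlation). Of 28 interferon-stimulated genes 15 fell and 6 rose, or 16 and 6 over the list alone (camera adjusted p = 0.0264, adjusted p = 0.346 with an estimated correlation). That list did not pass without either CIS-null ex vivo library (0.0622 and 0.0631).

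Several lists of markers of other cell types fell with culture. Of 20 monocyte and macrophage markers 17 fell and 1 rose, Cd68, or 18 and 1 over the list alone (camera adjusted p = 3.22e-12, adjusted p = 0.281 with an estimated correlation). Of 20 B cell markers 17 fell and 0 rose, the same over the list alone (camera adjusted p = 0.000334, adjusted p = 0.492 with an estimated correlation). Plasma cell markers (8 of 10 lower, 0 higher, the same over the list alone, camera adjusted p = 0.0202, adjusted p = 0.535 with an estimated correlation) and platelet markers (12 of 14 lower, 2 higher, the same over the list alone, camera adjusted p = 0.0236, adjusted p = 0.490 with an estimated correlation) fell as well. Both calls were lost without wild-type in vitro replicate 1 (0.0555 and 0.0594). The summed level of the platelet markers nonetheless went from 440.3 and 463.2 to 794.6 and 892.5 CPM. Erythroid (adjusted p = 0.139), neutrophil (0.211), basophil (0.218), dendritic cell (0.838) and T cell markers (0.879) did not pass. Summed T cell markers went from 772.6 and 797.7 to 1036 and 876.5 CPM, and neutrophil markers from 13.5 and 9.12 to 99.4 and 62.9 CPM. The neutrophil sum does not stand for the list: with the length trend removed, 7 of its 9 members fell and 1 rose.

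In CIS-null cells 4594 genes rose and 4945 fell on culture, 72.4% of those tested, and 2479 rose and 2732 fell at least 2-fold. Xist lay at 0.32 and 0.2 CPM ex vivo in these cells and at 130.7 and 89.7 CPM in vitro. The Y-linked genes went the other way, so an effect of culture cannot be told apart from sex here. With library totals as the scaling, which moved the median of all genes to -0.17, 4054 rose and 5436 fell. Of the lists, 13 were higher and 7 lower by camera, and with an estimated correlation 0 passed in either direction. The strongest were cholesterol and fatty acid synthesis (22 of 27 higher, 1 lower, camera adjusted p = 7.39e-21, adjusted p = 0.134 with an estimated correlation) and G2/M genes (28 of 30 higher, 0 lower, camera adjusted p = 2.79e-11, adjusted p = 0.338 with an estimated correlation). Over the list alone these counts were 22 and 1, and 29 and 0. Mature NK markers fell here too (12 of 15 lower, 3 higher, the same over the list alone, camera adjusted p = 7.88e-08, adjusted p = 0.297 with an estimated correlation).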

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

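Each result here was picked out because the genotype effect differed between ex vivo and in vitro cells by the interaction test (edgeR, adjusted p under 0.05). Of the tests weighed below, those on flanking DNA, on sex for the genes called in both comparisons and on the trend as the whole cause were chosen only after the result was seen. The largest differences were sex-linked: Xist 21.35 (adjusted p = 2.11e-06), Eif2s3y -13.83 (1.40e-05), Kdm5d -12.06 (6.52e-05), Ddx3y -12.99 (9.54e-05) and Uty -14.71 (9.54e-05) on the log2 scale, with Eif2s3x at 1.03 (0.0296). Apart from Eif2s3x, these values rest on groups with 0 to 3 counts and are not bounds. Since Xist and the Y-linked genes changed direction between the states, the differences in other genes and in lists cannot be told apart from an effect of sex. Sdc4 differed by -2.67 (0.000915), higher in CIS-null cells ex vivo (1.23) and lower in vitro (-1.45). Cd3g differed by 2.39 (0.0296), from -0.63 ex vivo to 1.77 in vitro. The other genes were Dscam -2.52, the X-linked Gm2223 1.11 and Il18r1 -1.22 (0.0296 each), Zhx2 -1.20 (0.0323), Lrrfip2 1.11 and Klrb1f -0.99 (0.0345 each), Srm 1.26 (0.0389), Tcf4 -1.13 (0.0427), Slc19a1 1.05 (0.0433) and Arl4d -1.25 (0.0492). By list the median differences were 0.828 for T cell markers, 0.522 for amino acid uptake, 0.282 for glycolysis, 0.218 for oxidative phosphorylation, 0.280 for cytotoxic genes, -0.543 for NK transcription factors, 0.135 for inhibitory receptors and -0.345 for G2/M genes. Their camera adjusted p ran from 2.51e-10 to 0.0497, and each had adjusted p = 0.807 with an estimated correlation. The cytotoxic median was -0.00258 without 4 members at the floor, and its call was lost with the length trend removed (0.103). The inhibitory receptor call was lost with the trend removed (0.872) and without wild-type ex vivo replicate 1 (0.0517) or 2 (0.0602), CIS-null ex vivo replicate 2 (0.161) or CIS-null in vitro replicate 2 (0.182). The NK transcription factor call was lost without CIS-null ex vivo replicate 2 (0.0835), wild-type in vitro replicate 1 (0.0653) or CIS-null in vitro replicate 2 (0.0893). The G2/M call was lost without wild-type ex vivo replicate 1 (0.190), CIS-null ex vivo replicate 2 (0.0815, turned), wild-type in vitro replicate 1 (0.0659) or CIS-null in vitro replicate 1 (0.326).

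Genes near Cish were weighed first. If DNA of another strain flanked the targeted allele, the odds of a call within 10 Mb would exceed those elsewhere. The odds ratio was 1.24 in vitro and its interval included 1, which does not exclude flanking DNA, since 1 near call ex vivo gave a wide interval and 25.9% of other genes were called in vitro. Of the 4 genes other than Cish called in the same direction in both comparisons, 3 lay within 20 Mb, where 2.09% of tested genes lie. This count was made after those genes were seen and tests nothing. If sex acted alike in both states, genes called in both would have opposite signs. Those near Cish, Rpl29, Tmem158 and Cxcr6, had the same sign, which excludes sex acting alike in both states as their sole cause. Their ex vivo changes were at least 8.13 standard errors, a size that follows from choosing called genes. Sex acting differently between the states was not tested and stays possible for them. Of neighbours called in either comparison 22.4% had opposite signs (95% interval 11.8 to 36.6, which includes the bound of 25). Among the 3257 autosomal genes called in vitro 78.5% had the same sign in both comparisons, so this share does not set the neighbours apart. For the neighbours sex cannot be told apart from an effect of CIS. Flanking DNA cannot be told apart from it for any of these genes.

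The number of genes called in vitro may have technical causes. Sex acting alike in both states is excluded as the whole cause: the slope of ex vivo on in vitro fold change was 0.156, where -0.617 was predicted. That prediction took the wild-type ex vivo cells as a mix with a male share of 0.383, from their Y-linked transcripts. The slope is a net value over many genes, so a part played by sex is not excluded. Sex acting only in culture was not tested. Removal of the length trend kept 61.4% of the calls in direction, between the bounds of 50 and 67, so its part cannot be told. The 2944 genes still called exclude the trend, as modelled here, as the whole cause. A trend that the model left in place is not excluded. Without the 50 most abundant genes 96.4% of calls were kept. The trimmed mean of M values already allows for a few genes taking reads, so this cannot exclude that cause. With library totals, which do not allow for it, 79.2% of calls were kept in direction. Loss of CIS itself stays possible and cannot be separated from sex in vitro.

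The CD3 and T cell receptor transcripts could come from T cells in the cultures or from the NK cells. If T cells were the source, Cd5, Cd6, Cd28, Themis and Trat1 would rise by a median log2 fold change of at least 1.77, which is 0.5 times that of Cd3e. Their median was 1.12, and 2 standard errors of a typical single member above it was 3.36, so the test could not tell. That spread is the median of the members' standard errors and not the error of their median. Cd5 was itself called higher (3.78, SE 1.12, edgeR adjusted p = 0.0394), but lost that call without any 1 wild-type library or CIS-null in vitro library (adjusted p from 0.0716 to 0.169) and on log2 RPKM (0.0809), and Cd6, Cd28, Themis and Trat1 did not pass.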

How the results depend on the processing

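The fits without X- and Y-linked genes, with the trend removed, without the 50 most abundant genes, on log2 RPKM, with crossed replicate numbers and of the SOCS list without Cish were chosen after results were seen. Ex vivo calls (4 higher, 4 lower) were 10 and 13 without the low-count filter, 20 and 20 by DESeq2, 1 and 2 on log2 RPKM, and ran from 1 to 22 and from 2 to 19 without 1 library; lower calls were 2 with the compared samples alone, 2 with a replicate block and 12 with the trend removed. In vitro calls (1445 and 1929) were 865 and 1061 on log2 RPKM, 744 higher with library totals, and ran from 187 to 1980 and from 313 to 2316 without 1 library. Interaction calls (7 and 11) were 37 and 38 without the filter, 214 and 365 by DESeq2, 1 and 5 with a replicate block, 0 and 1 (Sdc4) without X- and Y-linked genes, 107 and 102 with the trend removed and 0 and 0 on log2 RPKM. They ran from 1 to 96 and from 5 to 301 without 1 library; higher calls were 4 with library totals, 11 without immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes and 11 without the 50 most abundant genes. The cause was not tested.

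With an estimated correlation 0 lists passed as higher and 0 as lower in each of the 5 comparisons. Fry gave 0 and 0 ex vivo (camera 6 and 4), 3 and 1 in vitro (8 and 4), 0 and 0 for the interaction (6 and 2) and 14 lower in CIS-null culture (7). Without 1 library the ex vivo lists ran from 3 to 9 higher and from 3 to 8 lower, and the interaction lists from 5 to 8 higher and from 1 to 2 lower. Direction turned for G2/M genes (adjusted p = 4.75e-05, with 8.91e-24 to 0.170 over such fits) and B cell markers (1.92e-09, with 8.91e-24 to 0.254) ex vivo without CIS-null replicate 1, for the JAK-STAT list in vitro with the trend removed (0.962) and for the G2/M interaction without CIS-null ex vivo replicate 2 (0.0815, with 8.04e-16 to 0.326). Gzma in vitro had a log2 fold change of 0 on log2 RPKM and Socs7 of 0.16 with the trend removed. Genes lower in both states numbered 8 at an adjusted p under 0.1, against 3. The odds ratio near Cish was 35.4 ex vivo at 20 Mb (13.1 at 10 Mb) and 1.5 in vitro at 5 Mb (1.24). The cause was not tested for these. Differences between replicates showed no clear pairing by number (correlations from -0.232 to 0.146). These differences also carried length trends, so pairing is not excluded. A block with crossed numbers gave 9709 calls for CIS-null culture. Counts of 3 or fewer in a group limited fold changes to floors or wide intervals.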

Other observations

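The genes named here were chosen after their values were seen, and no explanation was tested for them. In cultured CIS-null cells Srm, the spermidine synthase gene, rose by a log2 fold change of 1.09 (SE 0.110, n = 2 per group, edgeR adjusted p = 0.00270), and Slc19a1, the reduced folate carrier, by 1.07 (SE 0.0976, edgeR adjusted p = 0.00200). Il18r1, a chain of the interleukin 18 receptor, fell by 1.2 (SE 0.106, edgeR adjusted p = 0.00191), and the repressor Zhx2 fell by 1.27 (SE 0.108, edgeR adjusted p = 0.00156). The labels place all 8 libraries in a group, and 0 sample columns were left unused.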
